A study of Rattus norvegicus with 6 samples.

How the data were processed

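RNA sequencing had been run on 6 libraries of cultured neonatal rat ventricular myocytes, 3 with a non-targeting control and 3 with a short hairpin RNA against Decr1. Per the labels' protocols, ventricular cells of newborn Sprague-Dawley rats were isolated with a cardiomyocyte kit. The cells that had not attached after 2 h were moved to a new dish and kept for 24 h in medium with 10% serum before the experiment. This step lowers, but need not remove, other heart cells. RNA was extracted with TRIzol and made into libraries with a VAHTS kit, and the labels put all 6 libraries in batch 1. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions. The genome build, gene annotation, gene lengths and strand setting are not given in the sources used here.

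The authors deposited 1 table of FPKM per gene symbol, with 1 column per library and no pooling of replicates, per the file headers. FPKM scales the fragments counted on a gene by the length of the gene and the size of the library. The table holds 30001 features, of which 22634 were above 0 in at least 1 library. Its values were found to be whole multiples of one step per feature for 22633 of those features, so whole reads and depths could be recovered. The tolerance was 1e-05 reads, and wider for large multiples. COX1 was the exception, beyond the range searched. The depths behind the FPKM were 39989800, 39659092 and 40108670 fragments in control replicates 1 to 3 and 37395826, 37413240 and 35290664 fragments in knockdown replicates 1 to 3. Recovered reads made up 96.4% to 98.2% of these depths. At this depth 3 reads on a gene of 1 kb stand for 0.0748 to 0.0850 FPKM, so values near 0 rest on few reads. Recovery was tested on 4000 simulated features, and 98.1% of those with at least 20 reads came out exactly. Replicates were compared before averaging. The chi-square of their recovered reads per feature was 6.85 to 11.9 within groups, where sampling noise alone gives 1, and 487 to 523 between groups, so no pair was counted as 1 library. Pearson's r across features was 0.996 within the controls, 0.997 within the knockdown libraries and 0.871 to 0.876 between the groups, with features not being independent replicates. The first principal component held 96.3% of the variance and the second 1.13%.

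Libraries were grouped by the treatment in the labels, and 1 comparison was made, knockdown against control. FPKM values were transformed as log2(FPKM + 1), and the 11975 features with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3. No covariate was used. P-values are two-sided with Benjamini-Hochberg adjustment, and the threshold is an adjusted p of 0.05. Fold changes on this scale understate the change of low genes. A count model was not used, since the values are FPKM. For Decr1 a two-sided exact permutation test of the 3 against 3 FPKM values was added. The fit was tested on simulated data for this comparison, with 11975 features of which 200 were changed, 50 at each size. It recovered 90% of the 1.5-fold rises, 98% of the 2-fold rises, 100% of the 4-fold rises and 100% of the falls to 0.5. It called 10 unchanged features and 0 of 30 simulated lists without change. The simulated features were drawn independently and few were changed. The list result therefore does not cover lists of correlated genes or a broad change. Changed features were drawn only from those above a floor of control expression, so the recovery does not cover low genes.

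In all, 28 gene lists for heart muscle, fatty acid metabolism, stress, immunity and the other cell types of a heart preparation were fixed before the data were examined. Of their 658 entries, 652 were found in the table. The 13 genes of mitochondrial DNA are listed there under other standard symbols and were matched after the table was seen. Another 4 symbols were matched through RefSeq synonyms. The 27 lists with at least 5 features tested were compared with all other features by camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. The erythroid list had 0 features above the filter. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

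Genes named in the text follow a rule fixed before the data were examined. It takes Decr1, then the 10 largest rises and the 10 largest falls among named genes past the threshold whose groups did not overlap, then up to 4 members of each list with the smallest adjusted p. This gave 127 genes, some of which are not reported here, and of which 123 were found in the RefSeq table of the GRCr8 assembly. Since the build behind the FPKM is not given in the sources used here, no coordinates are printed. By that annotation, 38 of the named genes overlap another gene and 14 overlap another protein-coding gene. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart.

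Alternatives fixed before the data were examined were a pseudocount of 0.1 or 0.5, no expression filter or one of 5 FPKM, median-ratio scaling, quantile normalization, limma without trend, the replicate number as a block, and leaving out each library in turn. For the lists they were camera with an estimated correlation and the rotation test fry. The voom method of limma on the recovered reads was added after the data were seen, as were 7 further gene groups described among the closing observations.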

Results

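Gene expression was measured by RNA sequencing in neonatal rat ventricular myocytes, primary heart muscle cells isolated from newborn Sprague-Dawley rats, in 6 libraries. In 3 libraries the cells had received a non-targeting control, and in the other 3 a short hairpin RNA against Decr1. Decr1 encodes the mitochondrial dienoyl-CoA reductase, an auxiliary enzyme in the β-oxidation of unsaturated fatty acids. The comparison asked which transcripts differed once Decr1 was knocked down in these cells. The libraries held between 39659092 and 40108670 fragments in the controls and between 35290664 and 37413240 in the knockdown. Expression is given as FPKM, a fragment count scaled by gene length and library size. Group values are the mean ± SD of 3 libraries. Log2 fold changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not say that the libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

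Decr1 was lower in each knockdown library than in each control library. It stood at 43.6, 44.3 and 42.8 FPKM in the controls and at 3.33, 1.24 and 2.36 FPKM in the knockdown libraries. These values rested on 2071, 2089 and 2041 reads and on 148, 55 and 99 reads. The mean was 43.6 ± 0.752 FPKM in controls and 2.31 ± 1.05 FPKM in the knockdown, so that 5.30% remained, with single libraries between 2.84% and 7.64%. The log2 fold change was -3.80 (SE 0.19, limma with Benjamini-Hochberg adjustment, adjusted p = 3.23e-08). A two-sided exact permutation test of the FPKM values gave p = 0.1, the smallest value that 3 libraries against 3 allow.

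Of the named genes, Cxcl10, Isg15 and Oasl, all on the interferon response list, had the largest rises, and Mfap4, Msln and Lbp the largest falls. Genes are ranked here and below on the log2(FPKM + 1) scale, and ratios of FPKM give another order. The chemokine gene Cxcl10 went from 3.03 ± 2.17 to 460.3 ± 5.01 FPKM, the ubiquitin-like modifier Isg15 from 6.76 ± 2.55 to 592 ± 37.8 FPKM. The controls were uneven for Cxcl10, with 80 to 251 reads per library. Oasl went from 2.06 ± 0.560 to 238 ± 4.24 FPKM. In the other direction, Mfap4, which encodes a microfibril-associated protein, went from 220.0 ± 13.9 to 1.40 ± 0.377 FPKM. Lbp, the gene of lipopolysaccharide-binding protein, went from 83.7 ± 4.83 to 0.454 ± 0.0351 FPKM. Msln, which encodes the mesothelial surface protein mesothelin, went from 99.3 ± 6.03 to 0.110 ± 0.0917 FPKM. The change was broad. Of 11975 features tested, 9678 changed, or 80.8% (limma, Benjamini-Hochberg adjusted p under 0.05). In the knockdown 5797 were higher and 3881 lower. Of these, 1306 were higher and 958 lower by at least 1 on the log2 scale. This balance turned to 974 higher and 1250 lower after median-ratio scaling, and to 1054 and 1143 after quantile normalization. The groups did not overlap for 9850 features (82.3%, where chance gives 10%). Higher features made up 59.9% of the calls on the FPKM as deposited, but 48.4% after median-ratio scaling and 52.2% after quantile normalization. The median log2 fold change of all features was 0.14 as deposited, -0.02 after median-ratio scaling and 0.03 after quantile normalization. Small shared shifts are to be read against this offset.

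**Figure D1:**
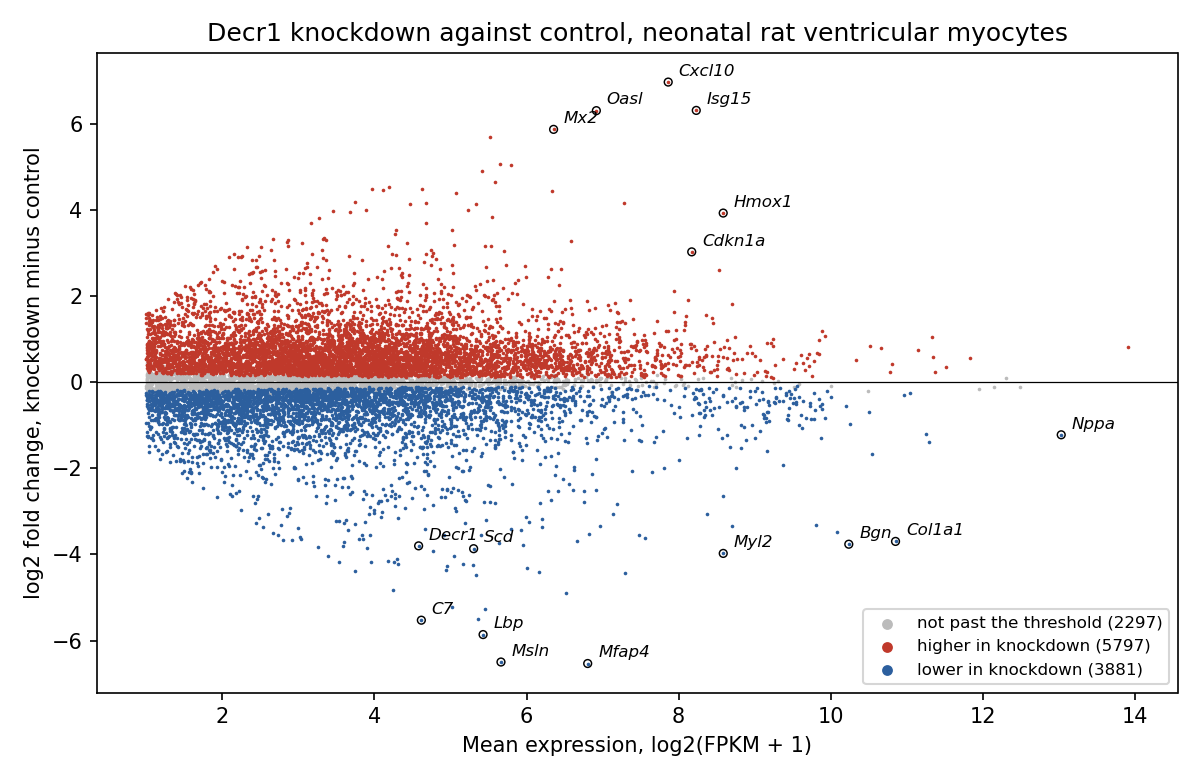
Log2 fold change (knockdown minus control) against mean expression, log2(FPKM + 1), for the 11975 features tested, with 1 point per feature. Red points are the 5797 features higher in the knockdown, blue points the 3881 lower and grey points the 2297 not past the threshold; Cxcl10 lies at 6.96 and Mfap4 at -6.53.

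Among the 10 genes with the largest rises were Cxcl10, Isg15, Oasl, Mx2, Rsad2, Gbp1, Bex1, Ifit3 and Usp18. The antiviral gene Rsad2 rose from 0.792 ± 0.496 to 89.2 ± 7.35 FPKM, and Mx2, which encodes an interferon-induced GTPase, from 2.00 ± 1.52 to 159.7 ± 14.7 FPKM. Control libraries held 77 to 211 reads for Rsad2 and 82 to 459 for Mx2, so these control means are uneven. Gbp1 rose from 1.95 ± 0.527 to 96.9 ± 1.82 FPKM, Ifit3 from 1.88 ± 1.09 to 81.3 ± 2.84 FPKM. Usp18, the protease that removes Isg15 from proteins, rose from 2.78 ± 1.22 to 91.4 ± 6.45 FPKM. Bex1, like Gbp1 not on the interferon list, rose from 2.27 ± 0.366 to 107 ± 12.8 FPKM. The 10 genes with the largest falls were Mfap4, Msln, Lbp, C7, Spon1, Pla2g2a, Fam180a, Serpinf1, Cpz and Cemip. In the same libraries the median log2 fold change of 15 fibroblast markers was -3.27. Spon1, which encodes a secreted matrix protein, fell from 79.3 ± 7.34 to 0.770 ± 0.0568 FPKM. Serpinf1, the gene of pigment epithelium-derived factor, fell from 176 ± 7.23 to 4.98 ± 0.598 FPKM. The hyaluronan-degrading Cemip fell from 76.3 ± 7.83 to 2.43 ± 0.12 FPKM. The secreted phospholipase gene Pla2g2a fell from 84.7 ± 12.5 to 1.25 ± 0.545 FPKM, Fam180a from 62.3 ± 5.46 to 0.720 ± 0.437 FPKM. Cpz, which encodes a carboxypeptidase, fell from 35.6 ± 2.09 to 0.298 ± 0.270 FPKM. The complement gene C7 stood at 47.0 ± 12.0 FPKM in controls, and 11 reads were left over the 3 knockdown libraries, too few for a fold.

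Among the gene lists fixed in advance, 9 stood higher and 5 lower than other genes, of 27 tested (camera in limma with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted). None of the 14 calls held with a correlation estimated from these libraries, which gave adjusted p between 0.133 and 0.542 for them. With that correlation 6 of the 27 lists had an unadjusted p under 0.05. The counts of members that rose or fell, 541 calls in all, came out the same in each of the 27 lists when adjusted over the list alone. With 80.8% of all features called, this agreement was likely in advance and lends the lists no further weight. Members named below as exceptions to the direction of a list, or as not past the threshold, were picked out after their values were seen.

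All 38 measured members of the interferon response list rose, with a median log2 fold change of 3.17 (camera in limma, Benjamini-Hochberg adjusted p = 3.12e-11; adjusted p = 0.387 with an estimated correlation). Cmpk2 rose from 0.763 ± 0.0751 to 26.9 ± 1.12 FPKM. Dhx58, which encodes a sensor of viral RNA, rose from 1.38 ± 0.176 to 40.8 ± 1.87 FPKM, and the guanylate-binding protein gene Gbp2 from 5.43 ± 0.188 to 33.6 ± 1.14 FPKM. NF-κB and inflammatory cytokine genes went both ways. Of these, 16 of 26 rose, 8 fell, and Il1a and Nfkb2 did not pass (adjusted p = 0.517 by camera in limma, Benjamini-Hochberg). The inducible nitric oxide synthase gene Nos2 rose from 0.153 ± 0.0406 to 10.5 ± 1.12 FPKM. Both leukocyte adhesion genes named by the rule fell, Vcam1 from 16.1 ± 0.953 to 3.38 ± 0.0828 FPKM and Icam1 from 69.7 ± 1.06 to 27.5 ± 1.57 FPKM. The complement gene C3 fell from 67.3 ± 0.942 to 2.64 ± 0.318 FPKM. Macrophage and leukocyte markers were mostly lower in the same libraries, as given with the other cell type markers, and the fibroblast markers had a median of -3.27.

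Most PPAR targets and most genes of mitochondrial β-oxidation were higher in the knockdown. In the list of PPAR targets and fatty acid handling, 15 of 16 members rose and Lpl fell, with a median log2 fold change of 1.43 (camera in limma, Benjamini-Hochberg adjusted p = 0.000328; adjusted p = 0.133 with an estimated correlation). Angptl4, which encodes an inhibitor of lipoprotein lipase, rose from 3.33 ± 0.397 to 75.3 ± 1.98 FPKM. Pdk4, the gene of a kinase that inactivates pyruvate dehydrogenase, rose from 2.29 ± 0.396 to 34.2 ± 1.8 FPKM. The lipid droplet gene Plin2 rose from 68.1 ± 0.159 to 259 ± 5.52 FPKM, and Ucp2 from 183 ± 9.97 to 644 ± 38.0 FPKM. Of 19 mitochondrial β-oxidation genes, 16 rose, Eci1 fell, and Echs1 and Etfb did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.00212; adjusted p = 0.542 with an estimated correlation). Cpt1b and Cpt1a encode forms of the carnitine palmitoyltransferase that commits fatty acids to mitochondrial import. Cpt1b rose from 13.7 ± 0.487 to 73.3 ± 0.674 FPKM and Cpt1a from 13.9 ± 0.807 to 40.4 ± 2.22 FPKM. Cpt1c, outside the list and looked up afterwards, fell from 6.57 ± 0.464 to 4.78 ± 0.398 FPKM. The thiolase gene Acaa2 rose from 45.5 ± 0.184 to 109 ± 3.66 FPKM. Etfa, which encodes a subunit of electron transfer flavoprotein, rose from 74.4 ± 2.60 to 188 ± 11.9 FPKM. Eci1, an isomerase that also acts on unsaturated fatty acids, went from 35.3 ± 1.97 to 20.4 ± 1.82 FPKM. These libraries also had all 15 fibroblast markers lower, with a median of -3.27.

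Peroxisomal β-oxidation genes moved both ways, with 8 of 14 higher (adjusted p = 0.84 by camera in limma, Benjamini-Hochberg). Acaa1a, Hsd17b4, Abcd3 and Crot were among the 5 that fell, and Pex5 did not pass. After median-ratio scaling 6 were higher and 6 lower. Ech1 rose from 25.2 ± 1.30 to 64.1 ± 2.69 FPKM and Scp2 from 64.7 ± 1.53 to 105 ± 2.81 FPKM. The thiolase gene Acaa1a fell from 19.6 ± 1.59 to 8.15 ± 0.287 FPKM. For triglyceride synthesis and lipolysis, 8 of 14 genes rose, G0s2 and Plin3 fell, and Gpam, Lpin1, Dgat1 and Lipe did not pass (adjusted p = 0.402 by camera in limma, Benjamini-Hochberg). With median-ratio scaling 6 rose and 5 fell, with quantile normalization 7 and 3. The gene of adipose triglyceride lipase, Pnpla2, rose from 29.3 ± 1.24 to 67.1 ± 0.788 FPKM. G0s2, which encodes an inhibitor of that lipase, fell from 60.9 ± 7.0 to 8.87 ± 1.45 FPKM. Cidea rose from 16.6 ± 0.766 to 41.9 ± 1.91 FPKM and the monoglyceride lipase gene Mgll from 4.93 ± 0.394 to 12.3 ± 0.645 FPKM. The median of the fibroblast markers was -3.27 beside both lists.

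Most genes of fatty acid and cholesterol synthesis fell. Of 26 members, 23 fell, Acacb rose, and 2 did not pass, Stard4 among them, with a median log2 fold change of -1.30 (camera in limma, Benjamini-Hochberg adjusted p = 1.48e-09; adjusted p = 0.161 with an estimated correlation). The stearoyl-CoA desaturase genes Scd and Scd2 fell, Scd from 72.9 ± 4.01 to 4.06 ± 0.272 FPKM and Scd2 from 592.7 ± 23.3 to 70.4 ± 1.59 FPKM. Fads1, a desaturase of polyunsaturated fatty acids, fell from 94.96 ± 1.91 to 26.3 ± 1.20 FPKM. The lanosterol synthase gene Lss fell from 75.0 ± 3.15 to 13.4 ± 1.02 FPKM. Fibroblast markers, with their median of -3.27, were lower in the same libraries.

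Most genes of glycolysis, of the TCA cycle and of the nuclear-encoded respiratory chain were higher in the knockdown. Glycolysis and lactate genes rose in 19 of 23 cases, while Pfkm, Aldoc and Slc16a1 fell and Pgam2 did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.00757; adjusted p = 0.542 with an estimated correlation). Pfkp rose from 39.3 ± 1.65 to 112 ± 3.08 FPKM, the lactate dehydrogenase gene Ldhb from 194 ± 4.75 to 504 ± 13.3 FPKM. Hk1 rose from 73.1 ± 1.45 to 159 ± 3.40 FPKM, and Pgam1 from 401 ± 5.00 to 808 ± 12.2 FPKM. In the list of the TCA cycle and pyruvate dehydrogenase, 22 of 26 genes rose, the pyruvate dehydrogenase kinase Pdk1 fell, and Dld, Suclg2 and Sdhc did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.00122; adjusted p = 0.429 with an estimated correlation). After either scaling 20 of these rose and 4 fell. Mitochondrial isocitrate dehydrogenase, Idh2, rose from 119 ± 2.03 to 371 ± 4.07 FPKM, and the succinate dehydrogenase subunit Sdha from 123 ± 2.00 to 243 ± 9.46 FPKM. Idh3g rose from 72.8 ± 1.34 to 138 ± 2.54 FPKM and Idh3a from 66.0 ± 1.26 to 124 ± 2.91 FPKM. All 15 fibroblast markers (median -3.27) and 7 of 8 epicardial, Schwann and neuronal markers fell in these libraries.

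Nuclear-encoded respiratory chain genes rose in 56 of 62 cases, with a median log2 fold change of 0.52 (camera in limma, Benjamini-Hochberg adjusted p = 5.69e-06; adjusted p = 0.429 with an estimated correlation). Ndufb10 and Atp5mc2 fell, and Ndufa2, Ndufa8, Ndufs6 and Ndufv2 did not pass. After median-ratio scaling 50 rose, 4 fell and the median was 0.33. The ATP synthase subunit Atp5f1b rose from 1046 ± 24.4 to 1869.7 ± 40.7 FPKM, Cox5b from 398 ± 21.0 to 742 ± 11.7 FPKM. Cyc1 rose from 134 ± 3.72 to 243 ± 7.49 FPKM, and Uqcrc1 from 154 ± 6.54 to 276 ± 7.15 FPKM. The 13 respiratory chain genes encoded in mitochondrial DNA went different ways. In this list 4 rose, ND3, ND4L and ATP8 fell, and 6 did not pass (adjusted p = 0.601 by camera in limma, Benjamini-Hochberg). After median-ratio scaling 3 rose and 8 fell, after quantile normalization 5 rose and 3 fell, and without control replicate 3 the numbers were 4 and 8. Their median was -0.11 as deposited, -0.30 after median-ratio scaling and 0.15 after quantile normalization. The direction of this group depended on the scaling, and its number of falls also on 1 control library. COX1 rose from 11183 ± 1049 to 19641 ± 1448 FPKM, ND6 from 36.7 ± 1.57 to 66.5 ± 6.05 FPKM and ND2 from 2065 ± 289.8 to 3105 ± 423 FPKM. ND4L, which overlaps ND4 on the mitochondrial genome, fell from 274 ± 120.4 to 59.4 ± 8.90 FPKM. Among mitochondrial biogenesis and dynamics genes, 12 of 19 rose, Tfb2m, Fis1, Pink1, Bnip3l and Fundc1 fell, and Dnm1l and Mff did not pass (adjusted p = 0.471 by camera in limma, Benjamini-Hochberg). The nuclear receptor gene Esrra rose from 22.1 ± 2.33 to 54.5 ± 1.93 FPKM, the coactivator Ppargc1b from 2.25 ± 0.347 to 6.87 ± 0.623 FPKM. Tfam, the mitochondrial transcription factor, rose from 19.95 ± 1.22 to 37.9 ± 3.08 FPKM. The mitophagy receptor gene Bnip3l fell from 13.6 ± 0.611 to 7.21 ± 0.234 FPKM. Across these libraries the fibroblast markers had a median of -3.27.

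Most p53 targets, cell cycle genes and antioxidant genes rose. In the list of p53 targets and apoptosis, 20 of 23 members rose, Zmat3 fell, and Sesn1 and Casp8 did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.000328; adjusted p = 0.133 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1a rose from 62.2 ± 2.13 to 512 ± 10.8 FPKM, Tp53inp1 from 10.7 ± 0.980 to 52.8 ± 1.57 FPKM. Mdm2, the gene of a ubiquitin ligase for p53, rose from 26.0 ± 1.39 to 69.7 ± 1.49 FPKM, and the nuclease gene Aen from 24.8 ± 2.15 to 70.3 ± 1.40 FPKM. Of 37 cell cycle genes, 34 rose, Ccnd1 and Cenpf fell, and Bub1 did not pass (camera in limma, Benjamini-Hochberg adjusted p = 5.69e-06; adjusted p = 0.299 with an estimated correlation). Both E-type cyclins rose, Ccne1 from 8.32 ± 0.311 to 82.6 ± 5.73 FPKM and Ccne2 from 1.13 ± 0.12 to 16.8 ± 1.19 FPKM. Mcm3, a subunit of the replicative helicase, rose from 16.0 ± 0.534 to 108 ± 3.34 FPKM and the thymidylate synthase gene Tyms from 11.3 ± 0.550 to 49.4 ± 1.47 FPKM. Ccnd1, which encodes cyclin D1, went from 69.5 ± 1.30 to 24.7 ± 1.78 FPKM. Antioxidant genes and NRF2 targets rose in 19 of 23 cases, with Gstm1, Sod2 and Gpx1 lower and 1 not past the threshold (camera in limma, Benjamini-Hochberg adjusted p = 0.00182; adjusted p = 0.299 with an estimated correlation). Heme oxygenase, Hmox1, rose from 46.7 ± 5.50 to 719 ± 4.05 FPKM, the sulfiredoxin gene Srxn1 from 18.4 ± 2.50 to 94.7 ± 3.55 FPKM. Catalase, Cat, rose from 46.4 ± 3.53 to 125 ± 7.64 FPKM, and glutathione reductase, Gsr, from 23.0 ± 0.256 to 65.0 ± 2.65 FPKM. Beside these rises the fibroblast markers fell, with a median of -3.27.

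Other stress-related lists had no shared direction past the camera test, in libraries where the fibroblast marker median was -3.27. Ferroptosis genes rose in 11 of 18 cases, with Acsl4, Aifm2 and Slc39a14 lower and Gpx4, Lpcat3, Tfrc and Sat1 not past the threshold (adjusted p = 0.31 by camera in limma, Benjamini-Hochberg). The balance was 7 higher and 5 lower with median-ratio scaling, and 9 and 5 with quantile normalization. The iron exporter Slc40a1 rose from 10.3 ± 0.642 to 91.7 ± 5.70 FPKM and the prostaglandin synthase gene Ptgs2 from 3.19 ± 0.367 to 38.0 ± 3.16 FPKM. Gch1 rose from 1.05 ± 0.0246 to 3.65 ± 0.285 FPKM and the ferritin heavy chain gene Fth1 from 1691 ± 135 to 2839 ± 82.7 FPKM. Unfolded protein and integrated stress response genes were split, with 13 of 28 higher and 11 lower (adjusted p = 0.601 by camera in limma, Benjamini-Hochberg). Atf4, Slc7a11, Sdf2l1 and Herpud1 did not pass. After median-ratio scaling 9 were higher and 14 lower. Atf5 fell from 147 ± 11.1 to 30.1 ± 2.27 FPKM and Aldh18a1, an enzyme of proline synthesis, from 33.8 ± 1.72 to 13.9 ± 0.0711 FPKM. Ppp1r15a rose from 31.7 ± 1.04 to 85.4 ± 2.39 FPKM and Mthfd2 from 34.4 ± 0.244 to 66.0 ± 2.22 FPKM. Immediate early genes rose in 13 of 22 cases and fell in 6, and Fosl2, Klf2 and Klf4 did not pass (adjusted p = 0.31 by camera in limma, Benjamini-Hochberg). Atf3 rose from 4.54 ± 0.252 to 33.5 ± 0.526 FPKM, Fosl1 from 1.49 ± 0.288 to 13.3 ± 0.247 FPKM. Btg2 rose from 13.2 ± 0.611 to 68.2 ± 1.77 FPKM and Zfp36 from 18.4 ± 0.694 to 47.8 ± 3.56 FPKM.

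Genes of the myocyte itself changed in both directions, in libraries with a fibroblast marker median of -3.27. Of 25 sarcomere genes, 13 rose, 9 fell, and Myl4, Myom1 and Nebl did not pass. The list had a median log2 fold change of 0.20, a mean of -0.41 and a camera test in the lower direction (limma, Benjamini-Hochberg adjusted p = 0.525). The balance turned to 8 higher and 12 lower after median-ratio scaling, with a median of 0.01. After quantile normalization the sarcomere median was 0.003. The ventricular regulatory light chain Myl2 fell from 721 ± 35.8 to 45.0 ± 5.06 FPKM, the slow myosin heavy chain Myh7 from 255 ± 15.1 to 35.3 ± 4.26 FPKM. The M-band gene Myom2 fell from 19.4 ± 1.37 to 1.18 ± 0.227 FPKM. The essential light chain Myl3 rose from 621 ± 7.59 to 1314 ± 8.37 FPKM. Calcium handling and excitability genes rose in 11 and fell in 11 of 25 cases, and 3 did not pass, Asph and Kcnq1 among them (adjusted p = 0.517 by camera in limma, Benjamini-Hochberg). Both connexin genes named by the rule fell, Gja5 from 51.0 ± 3.20 to 10.4 ± 1.10 FPKM and Gja1 from 75.9 ± 3.03 to 40.7 ± 0.973 FPKM. The T-type calcium channel gene Cacna1g fell from 8.02 ± 0.821 to 1.00 ± 0.0884 FPKM and the potassium channel gene Kcnh2 rose from 4.09 ± 0.375 to 11.6 ± 0.101 FPKM. Hypertrophy and fetal programme genes rose in 8 and fell in 8 of 18 cases, and Xirp2 and Hopx did not pass. The list had a median of -0.08, a mean of 0.30 and a camera test in the lower direction (limma, Benjamini-Hochberg adjusted p = 0.707). Skeletal α-actin, Acta1, rose from 91.2 ± 5.23 to 398 ± 12.7 FPKM, the secreted stress factor Gdf15 from 15.6 ± 2.92 to 293 ± 14.3 FPKM. Fhl1 rose from 139.8 ± 3.13 to 406 ± 19.6 FPKM, while Ankrd1 fell from 859.8 ± 30.4 to 283 ± 19.05 FPKM.

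**Figure D2:**
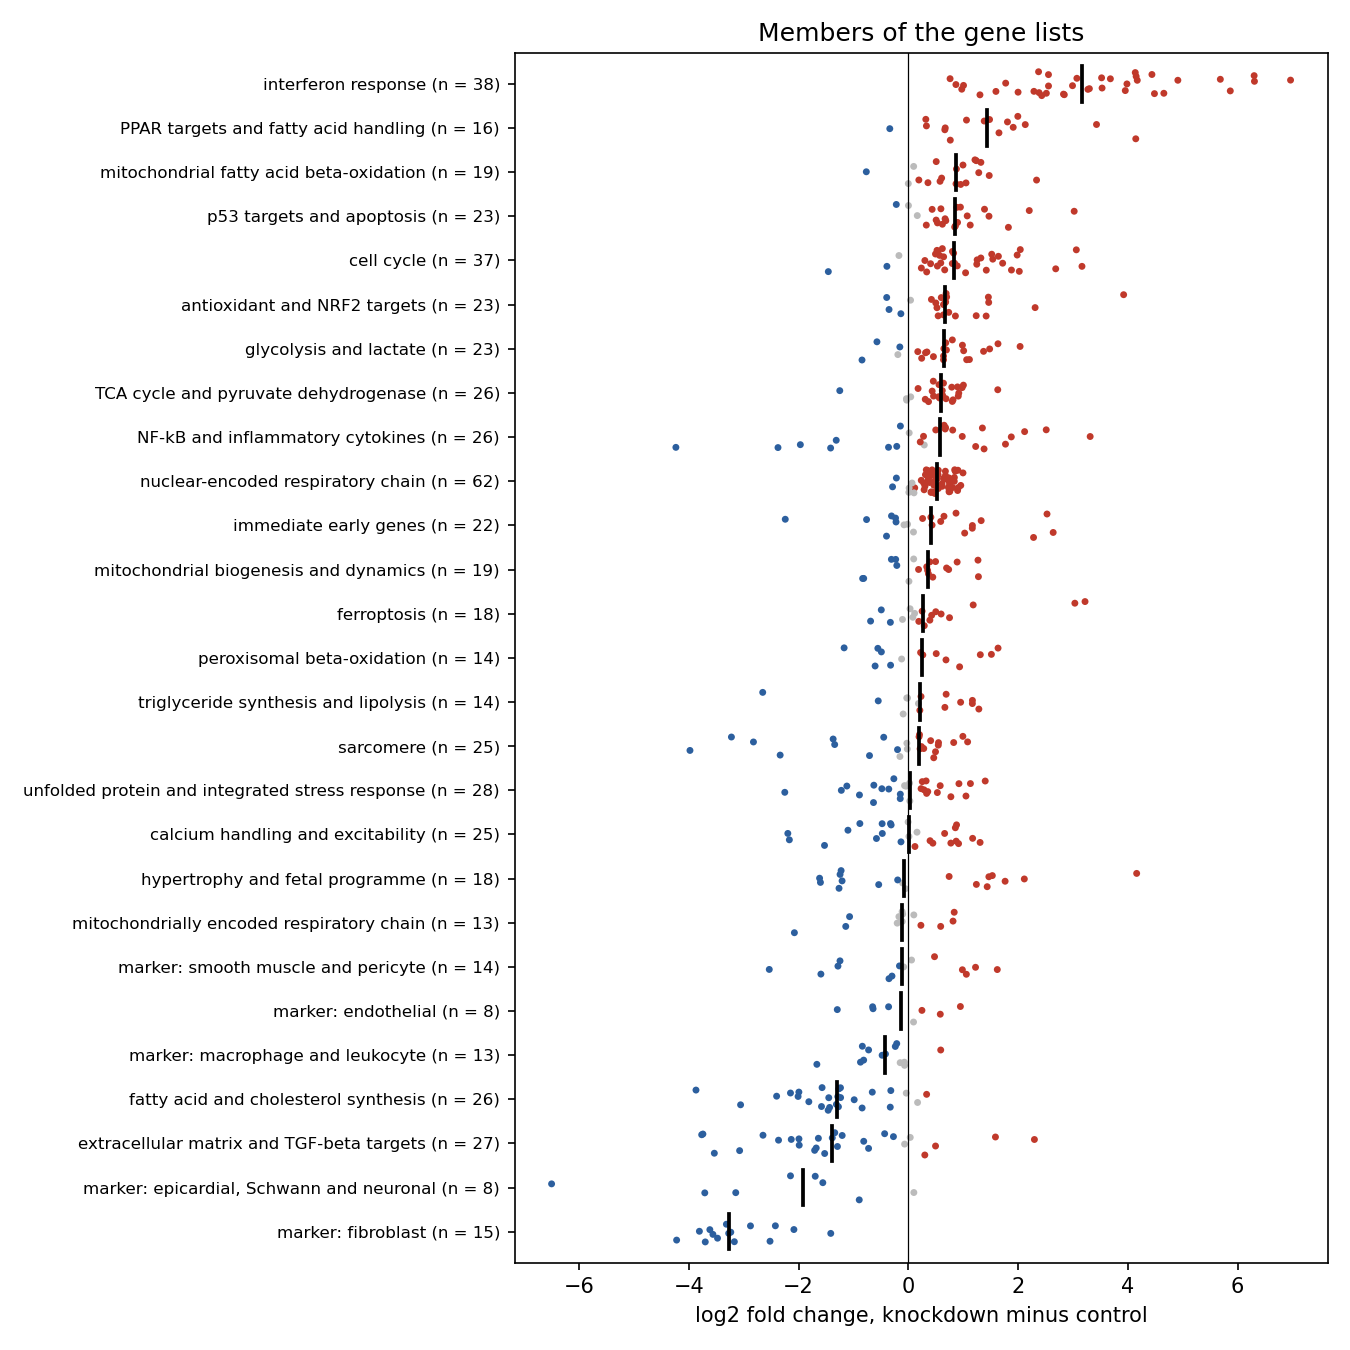
Log2 fold change (knockdown minus control) of each measured member of the 27 gene lists, with 1 point per gene and a black bar at the median of each list. Red and blue points rose and fell past the threshold and grey points did not pass; the interferon response list has its median at 3.17 and the fibroblast markers at -3.27.

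Markers of fibroblasts, the main other cell type of a neonatal heart preparation, fell in all 15 cases, with a median log2 fold change of -3.27 (camera in limma, Benjamini-Hochberg adjusted p = 9.19e-10; adjusted p = 0.133 with an estimated correlation). The collagen genes Col1a1 and Col1a2 fell from 3428 ± 226 to 263 ± 20.4 FPKM and from 1986 ± 129.2 to 178 ± 12.0 FPKM. Periostin, Postn, fell from 347 ± 20.1 to 27.4 ± 2.17 FPKM and fibulin, Fbln1, from 27.4 ± 1.30 to 1.41 ± 0.0104 FPKM. Extracellular matrix genes and TGF-β targets fell beside them in 21 of 27 cases, while Tgfb2, Mmp3, Tnc and Spp1 rose and 2 did not pass, Loxl2 among them (camera in limma, Benjamini-Hochberg adjusted p = 3.36e-07; adjusted p = 0.21 with an estimated correlation). Biglycan, Bgn, fell from 2246 ± 35.8 to 164 ± 6.21 FPKM, fibrillin, Fbn1, from 207 ± 4.69 to 16.9 ± 0.716 FPKM. The gelatinase gene Mmp2 fell from 659 ± 18.9 to 104 ± 4.63 FPKM and Col6a1 from 249.7 ± 16.2 to 28.7 ± 1.08 FPKM. Epicardial, Schwann and neuronal markers fell in 7 of 8 cases and Dbh did not pass, in the libraries in which fibroblast markers were lower (camera in limma, Benjamini-Hochberg adjusted p = 0.000149; adjusted p = 0.133 with an estimated correlation). Besides Msln, the mesothelial genes Upk3b and Lrrn4 fell from 21.6 ± 2.30 to 0.723 ± 0.0916 FPKM and from 29.6 ± 2.57 to 2.45 ± 0.241 FPKM. The neuronal tubulin gene Tubb3 fell from 41.5 ± 1.49 to 8.59 ± 0.310 FPKM.

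Macrophage, endothelial and smooth muscle markers had smaller medians, of -0.42, -0.13 and -0.12. These were -0.60, -0.25 and -0.30 after median-ratio scaling, and -0.56, -0.19 and -0.20 after quantile normalization. Of the macrophage and leukocyte markers, Adgre1, Cd163, C1qb, C1qc and Cd74 lay below the expression filter. Those above it fell in 9 of 13 cases, Coro1a rose, and Cd68, Ptprc and Itgam did not pass. Their median stood beside the -3.27 of the fibroblast markers (camera in limma, Benjamini-Hochberg adjusted p = 0.00757; adjusted p = 0.464 with an estimated correlation). Lysozyme, Lyz2, fell from 408 ± 31.1 to 232 ± 22.4 FPKM, Csf1r from 19.5 ± 1.55 to 10.2 ± 1.03 FPKM. Cd14 fell from 47.0 ± 3.50 to 28.1 ± 2.81 FPKM and C1qa from 6.03 ± 1.09 to 1.20 ± 0.12 FPKM. Of 8 endothelial markers above the expression filter, Kdr, Flt1 and Esam rose, Tie1, Tek, Egfl7 and Eng fell, and Cdh5 did not pass (adjusted p = 0.475 by camera in limma, Benjamini-Hochberg). Kdr stood at 2.85 ± 0.286 and 6.43 ± 0.485 FPKM in controls and knockdown, Flt1 at 4.35 ± 0.204 and 7.02 ± 0.612 FPKM. Tie1 stood at 3.41 ± 0.205 and 1.82 ± 0.109 FPKM, and Eng at 156 ± 16.9 and 62.7 ± 3.03 FPKM. Smooth muscle and pericyte markers rose in 5 and fell in 7 of 14 cases, and Tagln and Lmod1 did not pass (adjusted p = 0.488 by camera in limma, Benjamini-Hochberg). Pdgfrb fell from 144 ± 6.22 to 24.0 ± 1.83 FPKM. Cspg4 rose from 7.61 ± 0.595 to 25.5 ± 1.70 FPKM, Cnn1 from 88.0 ± 2.58 to 207 ± 10.6 FPKM. Des, which myocytes also express, rose from 614 ± 30.5 to 1215 ± 18.7 FPKM. None of the 12 erythroid markers reached the filter of a mean of 1 FPKM.

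**Figure D3:**
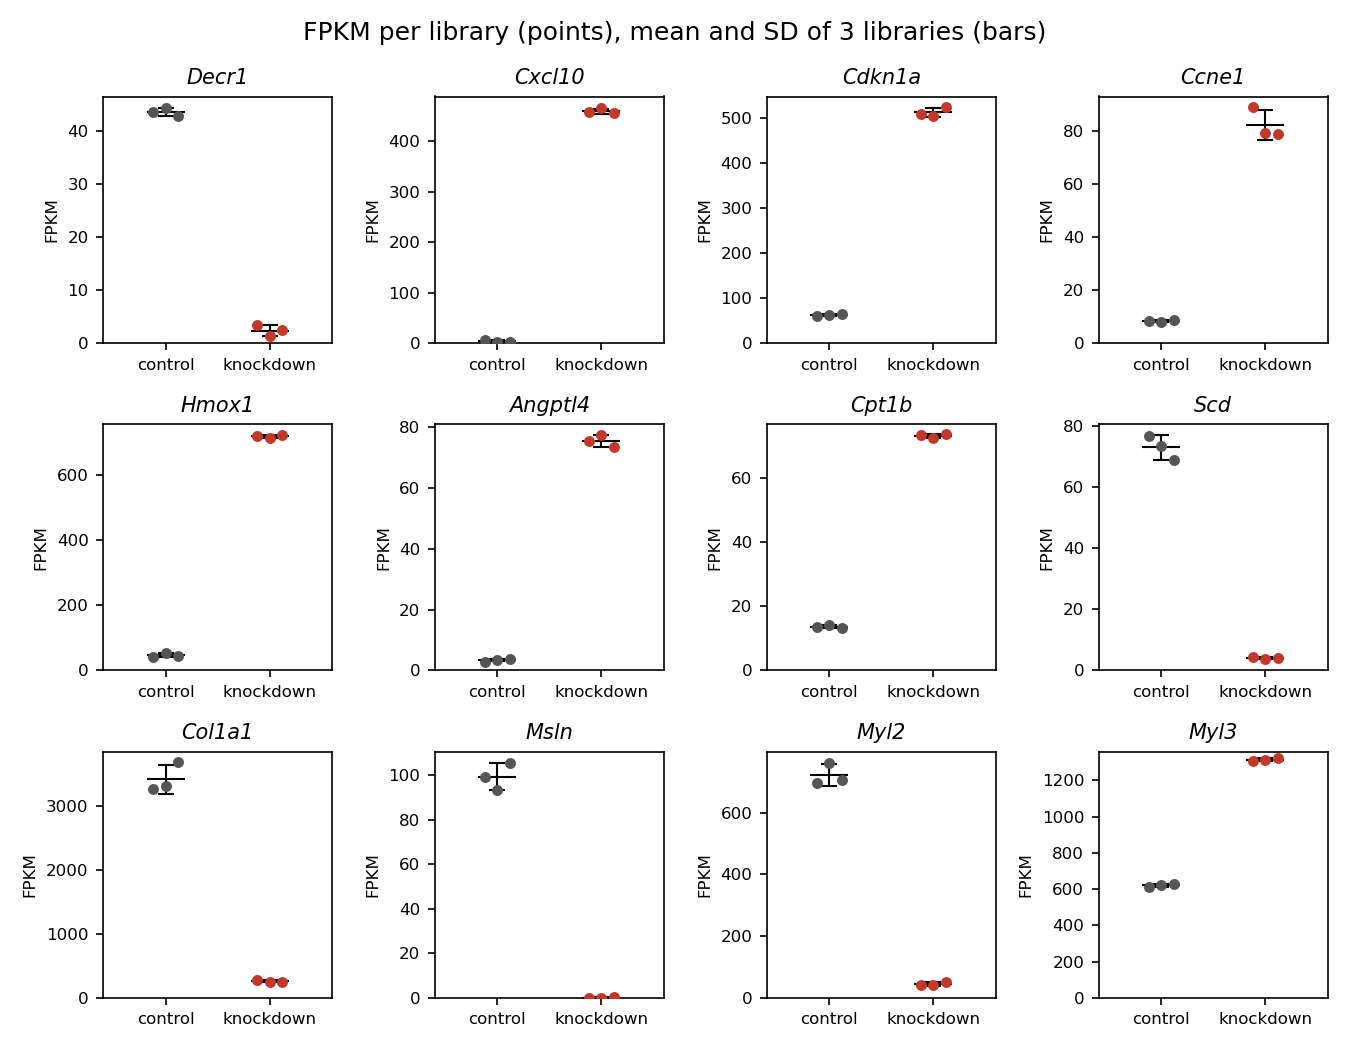
FPKM of 12 named genes in each library (points), with the mean and SD of the 3 control and the 3 knockdown libraries (bars), on linear axes that start at 0. Decr1 lies between 42.8 and 44.3 FPKM in controls and between 1.24 and 3.33 FPKM in the knockdown.

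Over the 127 named genes, the SE of the log2 fold change lay between 0.04 and 0.30, and the largest adjusted p was 0.000714 (limma, Benjamini-Hochberg). Values of Acaa1a, Atf3, Atf5, Ccne2, Col1a1, Cspg4, Cxcl10, Ech1, Esrra, Gdf15, Myh7, Pla2g2a and Slc40a1 are less certain, since each overlaps another protein-coding gene. So are those of the Gbp, Mx, Oas and Ifit families, whose close copies can share reads.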

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

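The voom fit was chosen after the results were seen; all other alternatives here were planned. For the 126 named genes other than Decr1, all 1883 values recomputed under the alternatives kept their direction and their side of the threshold, as did all 15 for Decr1. These genes were picked for large changes or small adjusted p, so this was likely in advance and does not speak for other calls. Of the 9678 calls of the main fit, 8495 were shared after median-ratio scaling and 8839 after quantile normalization. The number of changed features was 9642 and 9670 with pseudocounts of 0.1 and 0.5, 9527 after median-ratio scaling, 9554 after quantile normalization and 9641 without trend. It was 9742 with voom on the recovered reads. It was 11970 with no filter and 6846 with a filter of 5 FPKM, which test more and fewer features. The counts of features changed by at least 1 on the log2 scale, 1306 higher and 958 lower, depended more on the pseudocount. They were 1547 and 1101 with a pseudocount of 0.5, 1759 and 1245 with 0.1, and 1830 and 1289 with voom. Leaving out 1 library at a time gave 9241 to 9494 changed features, a Decr1 log2 fold change of -4.02 to -3.55, and 14 lists past the threshold each time. With the replicate number as a block (replicate block) 9574 features changed and 14 lists passed. Same-numbered libraries did not deviate together (r of -0.00, 0.07 and -0.07), and 0 of the 3 controls correlated best with their own number. No pairing by number was seen, though 3 libraries per group are too few to exclude one.

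For the lists, 436 of 458 recomputed tests kept their side of the threshold, 8 of them, all not past it, in the other direction. The other 22 came from a change of test, 14 lost and 8 gained. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower (6 at an unadjusted p under 0.05). A higher correlation is argued against as the cause for the PPAR, p53 and epicardial lists. Their estimates of -0.025, 0.014 and -0.013 lay near or below the preset 0.01, yet this camera test gave each an adjusted p of 0.133. Other lists that were lost had higher estimates, up to 0.49 for the interferon list, and the cause was not tested further. The adjusted p given with an estimated correlation is therefore not to be read as an effect of correlation alone. Fry, which asks only whether a list moves one way and does not compare it with other genes, called 22 lists, 15 higher and 7 lower. Among the 8 gained, the hypertrophy list turned to higher (adjusted p = 0.000684). After scaling, the list medians of calcium handling (-0.13 median-ratio, -0.06 quantile) and of the unfolded protein response (-0.13, -0.09) fell below 0, and that of the mitochondrially encoded genes rose to 0.15 after quantile normalization. That of the hypertrophy genes was -0.25 after median-ratio scaling, -0.21 after quantile normalization and -0.01 without control replicate 2. It was 0.34 with a filter of 5 FPKM, which tests fewer of them. Depth limits genes such as C7 and Msln, with 11 and 26 reads over the knockdown libraries.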

Other observations

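The gene groups in the first and second paragraphs, and all tests in this part except the splits of the samples, the check of gene length and the median-ratio scaling, were chosen after the results were seen. The camera values of these groups, adjusted over the added groups only, describe them and test no hypothesis. Most cytosolic ribosomal protein genes fell and most proteasome subunits rose, in libraries in which all 15 fibroblast markers fell (median -3.27). Of 85 cytosolic ribosomal protein genes, 73 fell and 7 rose, with a median log2 fold change of -0.48 (camera in limma, Benjamini-Hochberg adjusted p = 6.5e-12 over 7 added groups; adjusted p = 0.0613 with an estimated correlation). Rplp0 went from 1616 ± 74.8 to 819 ± 37.5 FPKM and Rpl3 from 726 ± 16.5 to 408 ± 6.74 FPKM. Of 37 proteasome subunits, 35 rose, Psmd10 fell and Psmd4 did not pass, with a median of 0.50 (adjusted p = 4.16e-05 by camera in limma, Benjamini-Hochberg; adjusted p = 0.0356 with an estimated correlation). The immunoproteasome subunit Psmb9 rose from 4.67 ± 0.0714 to 46.8 ± 4.67 FPKM and Psmb8 from 14.3 ± 1.52 to 78.2 ± 5.02 FPKM, both also members of the interferon list. Psma1, a subunit of the constitutive core, rose from 73.1 ± 3.06 to 137 ± 0.978 FPKM. Counts adjusted over the list alone were the same for both groups. Median-ratio scaling left the ribosomal median at -0.67 and the proteasome median at 0.31. Of 17 RT1 genes of the MHC class I region, 16 rose (17 adjusted over the list alone), with a median of 1.46 (adjusted p = 4.28e-05 by camera in limma, Benjamini-Hochberg; adjusted p = 0.103 with an estimated correlation). RT1-S3 went from 6.09 ± 0.726 to 45.4 ± 0.867 FPKM, though RT1 genes are near copies that can share reads.

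Most complement and insulin-like growth factor genes fell in the libraries in which the fibroblast markers fell, with their median of -3.27. Of 12 complement genes, 10 fell and C2 and Cfb rose (adjusted p = 0.00011 by camera in limma, Benjamini-Hochberg; adjusted p = 0.098 with an estimated correlation). C1s went from 327 ± 32.1 to 26.9 ± 3.68 FPKM and C1r from 323 ± 26.5 to 75.2 ± 4.80 FPKM, while Cfb went from 2.88 ± 0.602 to 7.48 ± 0.539 FPKM. Of 14 genes of the insulin-like growth factor axis and imprinted growth genes, 10 fell, Cdkn1c and Mest rose, and Igf1r and Igf2r did not pass (adjusted p = 0.000419 by camera in limma, Benjamini-Hochberg; adjusted p = 0.0908 with an estimated correlation). Igf1 went from 34.7 ± 4.48 to 2.99 ± 0.215 FPKM and Igf2 from 11.3 ± 1.35 to 0.590 ± 0.0646 FPKM. Cdkn1c, the gene of a cyclin-dependent kinase inhibitor, went from 2.09 ± 0.643 to 63.2 ± 4.56 FPKM. For both groups the counts adjusted over the list alone were the same.

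The number of changed features, 9678, was large. Of the 10 splits of the 6 libraries, 1, the real one, gave as many, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. A trend with gene length is argued against as the whole cause, since 9689 features were called after it was removed (Spearman's rho of the fold change with length, across genes, was -0.004). Scaling of the FPKM is likewise argued against as the whole cause of this number, with 9527 calls after median-ratio scaling. Single calls did depend on it, since 8495 were shared with the main fit and higher calls went from 5797 to 4614. Effects of the reagent and of other cell types stay open, as weighed for the patterns that follow.

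The fall of the fibroblast markers was larger than that of the macrophage markers. A loss of all non-myocyte cells alike is argued against, since the median log2 fold change was -0.4168 for macrophage markers and -3.27 for fibroblast markers (permutation test over genes, two-sided, p = 7e-05, genes not being independent). This covers the macrophage markers above the filter, which left out Adgre1, Cd163, C1qb, C1qc and Cd74. Among those measured, C1qa fell 5.03-fold, while Coro1a rose. Epicardial, Schwann and neuronal markers had a median of -1.92, endothelial markers one of -0.13 and smooth muscle markers one of -0.12. A loss that reached several of these cell types unequally stays open. With no filter the macrophage median was -0.33, on a scale that understates the change of low genes. After median-ratio scaling the fibroblast median was -3.441. That scaling moved the median of all features only from 0.14 to -0.02, so this outcome was likely in advance. An offset of that size is too small to account for the fall. Fewer fibroblasts in the knockdown cultures and lower expression within fibroblasts or myocytes cannot be told apart. Of the 13 markers with at least 10 FPKM in controls, 0 failed to fall, by 5.96-fold to 35.5-fold, and bulk RNA holds no count of cells.

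For the rise of the interferon response genes, more leukocytes in the knockdown cultures are argued against only as far as the markers cover them. Macrophage and leukocyte markers above the filter had a median log2 fold change of -0.4168. Of these 13, 9 fell, Coro1a rose, and Cd68, Ptprc and Itgam did not pass. With no filter 1 rose and 12 fell, some of them at low values. A response to the knockdown reagent rather than to the loss of Decr1 may account for the rise, and so may the loss of Decr1 itself. These cannot be told apart here, because the labels name 1 Decr1 reagent. The loss of Decr1 therefore remains one of the open explanations.

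The cell cycle list was split into replication and G1/S genes and mitotic genes after their values were seen. The 15 replication and G1/S genes had a median log2 fold change of 1.72, with 14 higher and Ccnd1 lower, and the 22 mitotic genes one of 0.58, with 20 higher and Cenpf lower (permutation test over genes, two-sided, p = 3e-05). This p restates the difference that prompted the split, on the same genes and libraries, and so tests no hypothesis. By camera in limma their Benjamini-Hochberg adjusted p were 4.16e-05 and 0.00132, and with an estimated correlation adjusted p = 0.0356 and 0.25. The camera values are likewise for groups formed after their values were seen, and test no hypothesis either. The medians were 1.56 and 0.41 after median-ratio scaling.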
